A study of Mus musculus with 4 samples.

How the data were processed

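RNA from subcutaneous white adipose tissue of C57BL/6 mice given BML-260 or vehicle was extracted with TRIzol and sequenced as Illumina libraries, per the labels' protocols. The authors deposited 1 table with 51912 genes and 4 libraries, vehicle A and B and BML-260 A and B, which were assigned to groups by their treatment label. The table holds expected counts per gene, which the authors deposited without normalization, as estimated counts that need not be whole; 76.5% to 77.8% of values above 0 were whole, with no decimals at all. It also holds FPKM values, per the file headers, and the group means of counts and of FPKM as the authors deposited them, those of FPKM also on a log2 scale. The authors' own comparison is deposited as a log2 fold change, a p-value and an adjusted p-value per gene. The submitters' processing notes name HISAT2 2.1.0, RSEM 1.2.31, DESeq2 1.10.1 and the build GRCm38.p5, without role or order. The annotation, strand setting and read filters were not given in the sources used here. Without a stated strand setting, overlapping and antisense genes, and near-identical family members, have uncertain counts. Such genes include the mitochondrial ones with nuclear copies.

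Expected counts were rounded to whole numbers. Of the gene identifiers, 51633 matched GENCODE vM21 annotation of GRCm38, which gave coordinates and gene types, and 279 did not. A spreadsheet had turned 27 symbols into dates, of which 26 were restored by identifier. For 97 symbols on more than 1 identifier, the one with the highest mean count stood for the symbol in gene lists. Genes with low counts were removed with filterByExpr, which left 15643. The main test was edgeR 4.0.16 quasi-likelihood (R 4.3.3) with TMM factors, group as the only term, two-sided, with Benjamini-Hochberg adjustment at 0.05. There were 2 residual degrees of freedom and 3.28 prior ones, and the biological coefficient of variation was 23.0%. Standard errors are the log2 fold change divided by the square root of F. Levels are TMM-scaled CPM. Intervals of reads cover counting error only.

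Before the data were examined, 41 gene lists were fixed: 24 of responses, 14 of other cell types and 3 of RNA quality or sex. The 40 with at least 5 tested members were tested with camera (limma 3.58.1) on voom values at its preset correlation of 0.01. The genes named were also fixed by a rule: up to 10 genes per direction past the threshold with no overlap of groups, or the 5 with the smallest p where none passed; the 4 members with the smallest p of every called list; and Ucp1, Ppargc1a, Cidea, Dio2, Prdm16, Adrb3, Adipoq, Lep, Pparg, Fasn, Dusp22, Stat3, Creb1, Mapk8 and Socs3. This rule gave 84 genes, and Ckm, Ddx3y, Atp2a1 and Ryr1 were named after their values were seen. Of the 84, 2 are not reported here.

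The tests were tried on simulated counts for the BML-260 against vehicle comparison, with 50 genes planted at each fold and the spread estimated from these libraries. In 15395 genes edgeR recovered 42% of genes changed 2-fold, 88% at 4-fold, and 100% at 16-fold and at 30-fold, with 19 false calls. DESeq2 recovered 66%, 92%, 100% and 100%, with 56 false calls. The simulated genes varied independently, without differences in tissue content between libraries that many genes share, so these rates need not hold for the real data. There edgeR called 1 gene and did not call Dio2, which was 12.8-fold higher (edgeR adjusted p = 0.119). Alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, filters and thresholds, leaving out each library, the library letter as a term, fry, and camera with an estimated correlation. A muscle score (the mean log2 level of the skeletal muscle list) as a term, a robust prior, the thermogenic list without muscle-expressed members 2 forms of a muscle-expected level and their comparison with the 50 genes nearest in vehicle level were added after seeing the data. Adjusted p-values that DESeq2 left missing stayed missing. Replicate libraries differed by more than counting noise, so each counted as 1 sample.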

Results

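Gene expression was measured by RNA sequencing in subcutaneous white adipose tissue, the fat depot under the skin, of 8-week-old C57BL/6 mice. Mice were treated with BML-260, a compound known as an inhibitor of the phosphatase DUSP22 (also called JSP-1), or with the vehicle dimethyl sulfoxide. There were 4 libraries, 2 per treatment, labelled A and B. The series speaks of 8 mice, 4 per treatment, and how these mice map onto the 4 libraries was not given in the sources used here, so p-values measure only the spread between these libraries. Total expected counts were 20407836 in vehicle A, 23032466 in vehicle B, 19999836 in BML-260 A and 23726781 in BML-260 B. Levels are given as CPM, counts scaled to the size of each library. Of 51912 genes in the table, 15643 had enough counts to be tested. The only comparison of the design was BML-260 against vehicle, which asks how treatment with the compound changed the adipose transcriptome.

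Ucp1, the mitochondrial proton carrier that lets brown and beige adipocytes turn fuel into heat, rose 29.2-fold with BML-260 (95% confidence interval 21.5 to 39.6). Its level was 8.78 ± 1.27 CPM with vehicle and 257 ± 8.50 with BML-260 (SD, n = 2 each), from 166 and 224 reads per vehicle library and 5203 and 5764 per BML-260 library. Many other genes of thermogenic adipocytes lay higher in both BML-260 libraries, among them Dio2, which activates thyroid hormone locally, Cpt1b, which carries fatty acids towards oxidation, and Acot11, a thioesterase induced in brown fat by cold. Genes of white adipocyte function, among them Agt, Retn and Acly, lay lower. Skeletal muscle transcripts also differed strongly between the libraries, from 0.0586% of counts in vehicle A to 5.59% in BML-260 B, and their values are given beside the gene groups that moved with them.

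Ucp1 (ENSMUSG00000031710) lies on chromosome 8 at 83290352 to 83298452 on the plus strand of GRCm38 and is annotated as protein coding. Its log2 fold change was 4.87 (SE 0.17) with an adjusted p of 0.00969 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It was the only gene of the 15643 to pass an adjusted p of 0.05 in that test, with 1 gene higher and 0 lower. At an unadjusted p under 0.05 the same test counted 1165 genes higher and 564 lower. DESeq2 called 327 genes higher and 78 lower, and limma-voom called 1 higher and 0 lower. The authors' deposited table holds 288 genes higher and 69 lower at an adjusted p under 0.05. In the authors' deposited table, 356 of those 357 genes were also among the 405 that DESeq2 called here. Of the 327 genes that DESeq2 called higher, 134 already differed within the vehicle group, over 1.5-fold higher in vehicle B than in vehicle A. The same held for 109 of the 163 genes the authors marked higher with a log2 fold change of 1 or more. Among the 13132 genes with an average log2 CPM of 1 or more it held for 863. The values of the 2 groups did not overlap in 44.3% of tested genes, against 33.3% by chance for 2 libraries against 2. The call of Ucp1 was lost without vehicle A (log2 fold change 4.70) and with the library letter as a term (4.87, edgeR adjusted p = 0.129). It was also lost with the skeletal muscle score as a term of the model, an alternative chosen after seeing the data (4.59, edgeR adjusted p = 0.552). A fit with either term leaves 1 residual degree of freedom. The test called 309 genes without vehicle B, 5 without BML-260 B and 0 without vehicle A.

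**Figure D1:**
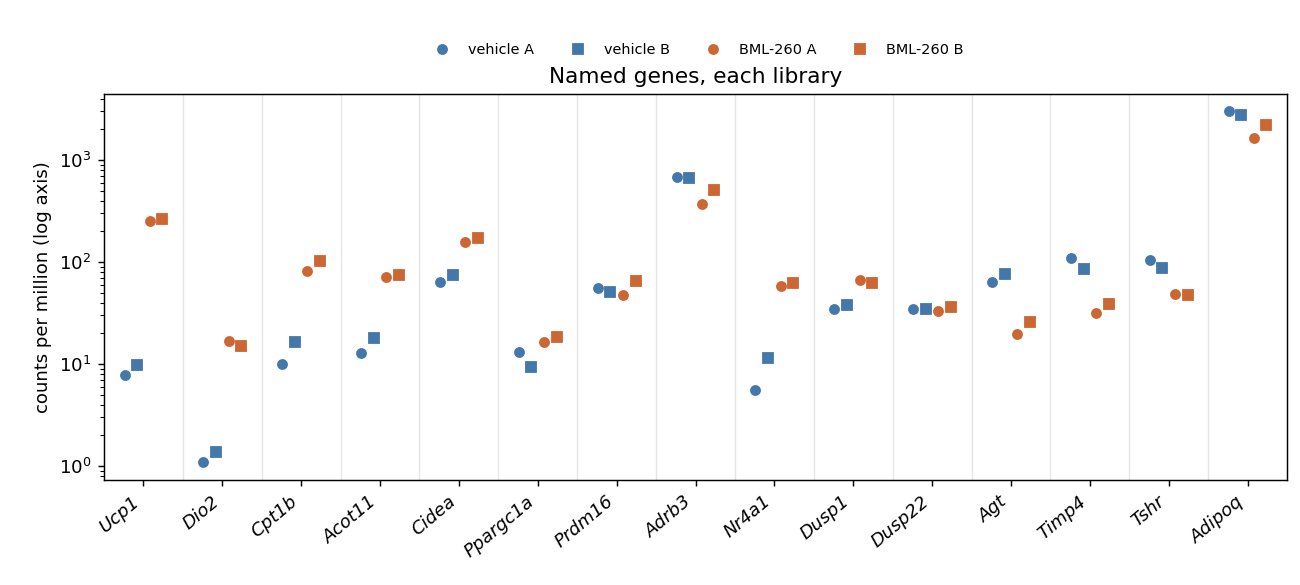
CPM of 15 named genes on a log axis, 1 point per library (circles for A, squares for B, blue for vehicle, orange for BML-260). Ucp1 lies at 7.88 and 9.68 CPM in the vehicle libraries and at 251 and 263 in the BML-260 libraries, while Dusp22 lies between 33.2 and 36.1 in all 4.

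The list of thermogenic brown and beige adipocyte genes rose as a group, with a median log2 fold change of 0.92 over 28 tested members and 24 of them above zero (camera with its preset correlation, adjusted p = 4.3e-13; adjusted p = 0.86 with an estimated correlation). Ucp1 alone of the list passed the edgeR test over all genes. Adjusted over the list alone, 17 members were higher and 1 lower, and DESeq2 called 12 higher and 1 lower. Dio2 had a log2 fold change of 3.68 (SE 0.24, edgeR adjusted p = 0.119), from 1.09 and 1.38 CPM with vehicle to 16.7 and 15.2 with BML-260. Cpt1b had a log2 fold change of 2.81 (SE 0.27, adjusted p = 0.216) and Acot11 of 2.25 (SE 0.19, adjusted p = 0.205). The lipid droplet protein gene Cidea lay at 64.5 and 74.6 CPM with vehicle and at 158 and 171 with BML-260, a log2 fold change of 1.24 (SE 0.14, adjusted p = 0.216). Ppargc1a, a coactivator of mitochondrial genes, had a log2 fold change of 0.64 (SE 0.22). Prdm16, a transcriptional regulator of brown and beige fat identity, had 0.09 (SE 0.18), and the beta-3 adrenergic receptor gene Adrb3 had -0.62 (SE 0.22). Skeletal muscle markers rose with the same libraries, and 8 of the 28 members are also expressed by striated muscle, Cpt1b and Ppargc1a among them. The other 20 members had a median log2 fold change of 0.59, with 16 above zero (camera adjusted p = 1.52e-07). With the muscle term the median of all 28 was 0.931 (camera adjusted p = 1.89e-13), in a fit with 1 residual degree of freedom. Both p-values are at the preset correlation, and neither check was run with an estimated one. For the full list without that term fry gave an adjusted p of 0.115.

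Mitochondrial fatty acid oxidation genes rose slightly as a group (median 0.16 over 24 members, 19 above zero, camera adjusted p = 0.00361; adjusted p = 0.895 with an estimated correlation). None of its 24 members passed the edgeR test over all genes, 5 reached an unadjusted p under 0.05 and 3 were called by DESeq2, with 3 higher adjusted over the list alone. Ppara, a nuclear receptor for fatty acids, had a log2 fold change of 1.04 (SE 0.12, adjusted p = 0.216), Acaa2 of 0.75 (SE 0.14) and Etfdh of 0.41 (SE 0.15). Without BML-260 B the list's median was -0.02 and its camera adjusted p 0.791, without BML-260 A the median was 0.32, and with the muscle term it was 0.197 (adjusted p = 0.122). Genes of heat-producing cycles that do not need UCP1 also rose as a group (median 0.31 over 16 members, 10 above zero, camera adjusted p = 0.0318; adjusted p = 0.86 with an estimated correlation). No member passed the edgeR test over all genes, 5 reached an unadjusted p under 0.05, DESeq2 called 2, and 3 were higher adjusted over the list alone. The glycerol kinase gene Gk had a log2 fold change of 1.36 (SE 0.17), with 6.50 and 6.57 CPM in vehicle and 17.0 and 16.6 in BML-260. Slc25a4, a mitochondrial ADP/ATP carrier gene, lay at 213 and 258 CPM with vehicle and 427 and 515 with BML-260, and Slc6a8 and Letmd1 had log2 fold changes of 0.53 and 0.45. This list also holds Atp2a1 and Ryr1, the calcium pump and release channel of skeletal muscle, at 2.63 and 2.83. Its call was lost without BML-260 B (adjusted p = 0.319) and with the muscle term (0.316, median 0.123), and its median was 0.195 without vehicle A.

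Mitochondrially encoded genes rose slightly as a group (median 0.18 over 15 members, 12 above zero, camera adjusted p = 0.0285; adjusted p = 0.895 with an estimated correlation). None passed the edgeR test over all genes, 3 reached an unadjusted p under 0.05, DESeq2 called 2 and 1 was higher adjusted over the list alone. mt-Co3 and mt-Nd4l had log2 fold changes of 1.23 (SE 0.17) and 1.15 (SE 0.27), and the ribosomal RNA genes mt-Rnr1 and mt-Rnr2 had 0.52 each; nuclear copies of mitochondrial sequence make single values in this list uncertain. These genes took 7.05% and 6.83% of counts in the vehicle libraries and 7.23% and 7.57% in the BML-260 libraries. Leaving out vehicle A (adjusted p = 0.191), vehicle B (0.0542) or BML-260 B (0.319, median 0.087) ended the call, as did the muscle term (0.287, median 0.121). Nuclear genes of the oxidative phosphorylation complexes had a median of 0.03 over 58 members (camera adjusted p = 0.85), with 0 called by edgeR or DESeq2 and 1 at an unadjusted p under 0.05. The BML-260 libraries went opposite ways in it, with medians of 0.168 without BML-260 A and -0.142 without BML-260 B. Its members moved together, with an estimated correlation of 0.902 and a camera adjusted p of 0.974 with it. Some called lists also had high estimated correlations, such as B cells (0.932), skeletal muscle (0.866) and cell cycle (0.848). Other called lists had low ones, such as the thermogenic list (0.067) and the cyclic AMP and CREB targets (0.093). The tricarboxylic acid cycle list had a median of 0.17 over 20 members (camera adjusted p = 0.0513, or 0.895 with an estimated correlation). Its median was 0.319 without BML-260 A, -0.009 without BML-260 B and 0.107 with library totals (camera adjusted p = 0.0215).

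Targets of cyclic AMP signalling and the transcription factor CREB rose as a group (median 0.72 over 22 members, 17 above zero, camera adjusted p = 1.57e-07; adjusted p = 0.86 with an estimated correlation). No gene of the list passed the edgeR test over all genes, 11 reached an unadjusted p under 0.05 with higher values, DESeq2 called 8 higher, and 9 were higher adjusted over the list alone. Nr4a1, an immediate early nuclear receptor gene, had a log2 fold change of 2.81 (SE 0.35, edgeR adjusted p = 0.219), from 5.51 and 11.6 CPM to 58.1 and 62.5. Sik1 and Dusp1, both induced by cyclic AMP, had log2 fold changes of 0.93 (SE 0.18) and 0.83 (SE 0.12). Creb1 itself lay at 0.17 (SE 0.19). The list shares Dio2 and Ppargc1a with the thermogenic list. Skeletal muscle markers were also higher in the BML-260 libraries. With the muscle term the list's median was 0.60 (camera adjusted p = 4.9e-04 at the preset correlation), in a fit with 1 residual degree of freedom.

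The MAP kinase phosphatase and JNK pathway list, which holds the compound's known target, rose as a group (median 0.22 over 24 members, 16 above zero, camera adjusted p = 0.0228; adjusted p = 0.86 with an estimated correlation). Of its members, 0 passed the edgeR test over all genes, while 7 were higher and 2 lower at an unadjusted p under 0.05, DESeq2 called 3 higher, and 4 were higher adjusted over the list alone. Dusp8, Jun and Dusp6 had log2 fold changes of 1.25 (SE 0.21), 0.84 (SE 0.17) and 0.56 (SE 0.14). Dusp22 transcripts stood at 35.0 and 35.0 CPM with vehicle and 33.2 and 36.1 with BML-260, a log2 fold change of -0.01 (SE 0.12, edgeR adjusted p = 0.978). Mapk8, which encodes JNK1, had 0.24 (SE 0.14). The call of this list was lost without vehicle A (adjusted p = 0.0751), vehicle B (0.0638) or BML-260 B (0.112, median 0.132) and with the muscle term (0.122, where the median was 0.29). Early response genes of the MAP kinase pathway rose as a group (median 0.41 over 26 members, 22 above zero, camera adjusted p = 8.05e-04; adjusted p = 0.86 with an estimated correlation). None of these passed the edgeR test over all genes or adjusted over the list alone, 7 were higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 2. Fos and the chemokine gene Ccl2 had log2 fold changes of 1.47 (SE 0.41) and 2.30 (SE 0.63), each with its highest value in BML-260 A. Without BML-260 A the early response list had a median of 0.204 and a camera adjusted p of 0.0506, and without BML-260 B the median was 0.616. BML-260 A is also the library with high B cell and T and NK cell markers (mean centred log2 levels 2.812 and 1.713, against -0.739 and -0.63 in BML-260 B). STAT3 targets had a median of 0.25 over 21 members (camera adjusted p = 0.0955), with Stat3 at 0.05 and Socs3 at 0.17. The STAT3 list was called at the preset correlation without vehicle B (median 0.359) and without BML-260 B (0.298), with 1 library left in a group. Its median was 0.094 without vehicle A and -0.036 without BML-260 A. With all libraries and an estimated correlation its camera adjusted p was 0.895.

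Genes of fatty acid and triglyceride synthesis fell as a group (median -0.34 over 23 members, 22 below zero, camera adjusted p = 1.35e-05; adjusted p = 0.86 with an estimated correlation). For single members, 0 passed the edgeR test over all genes or adjusted over the list alone, 3 were lower at an unadjusted p under 0.05 and DESeq2 called 2 lower. The desaturase genes Scd2 and Fads1 had log2 fold changes of -0.63 (SE 0.18) and -0.39 (SE 0.12). Acly, which makes cytosolic acetyl-CoA, had -0.72 (SE 0.28) and the lipogenic regulator gene Thrsp -0.57 (SE 0.28). Fasn, the fatty acid synthase gene, lay at -0.17 (SE 0.40), with 16084 and 20337 CPM in vehicle and 11789 and 20642 in BML-260. The list's median was -0.141 without BML-260 A, -0.554 without BML-260 B and -0.577 with the muscle term.

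Genes of mature adipocytes and adipokines fell as a group (median -0.25 over 24 members, 19 below zero, camera adjusted p = 2.54e-04; adjusted p = 0.86 with an estimated correlation). In the edgeR test over all genes 0 members passed, 5 were lower at an unadjusted p under 0.05, DESeq2 called 1, and Agt alone was lower adjusted over the list alone. Agt, which encodes angiotensinogen, had a log2 fold change of -1.64 (SE 0.18, edgeR adjusted p = 0.216), from 64.2 and 76.8 CPM to 19.6 and 25.7. Sfrp5, Retn and Acvr1c had log2 fold changes of -0.99, -0.69 and -0.56. The adiponectin gene Adipoq had -0.58 (SE 0.26), Pparg -0.37 (SE 0.21) and the leptin gene Lep -0.36 (SE 0.26), or -0.011 without vehicle A. The list's median was -0.108 without BML-260 A and -0.449 without BML-260 B, and its call was lost with the muscle term (adjusted p = 0.0538), where the median was -0.273. The 5 genes with the smallest unadjusted p among those lower with BML-260 were Ston1, Agt, Timp4, Tshr and Apod. Ston1 had a log2 fold change of -1.28 (SE 0.13), Timp4, a metalloproteinase inhibitor gene, -1.48 (SE 0.18), the thyrotropin receptor gene Tshr -1.01 (SE 0.14) and Apod -0.84 (SE 0.12). Their edgeR adjusted p values lay between 0.216 and 0.249, and DESeq2 called all 5.

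**Figure D2:**
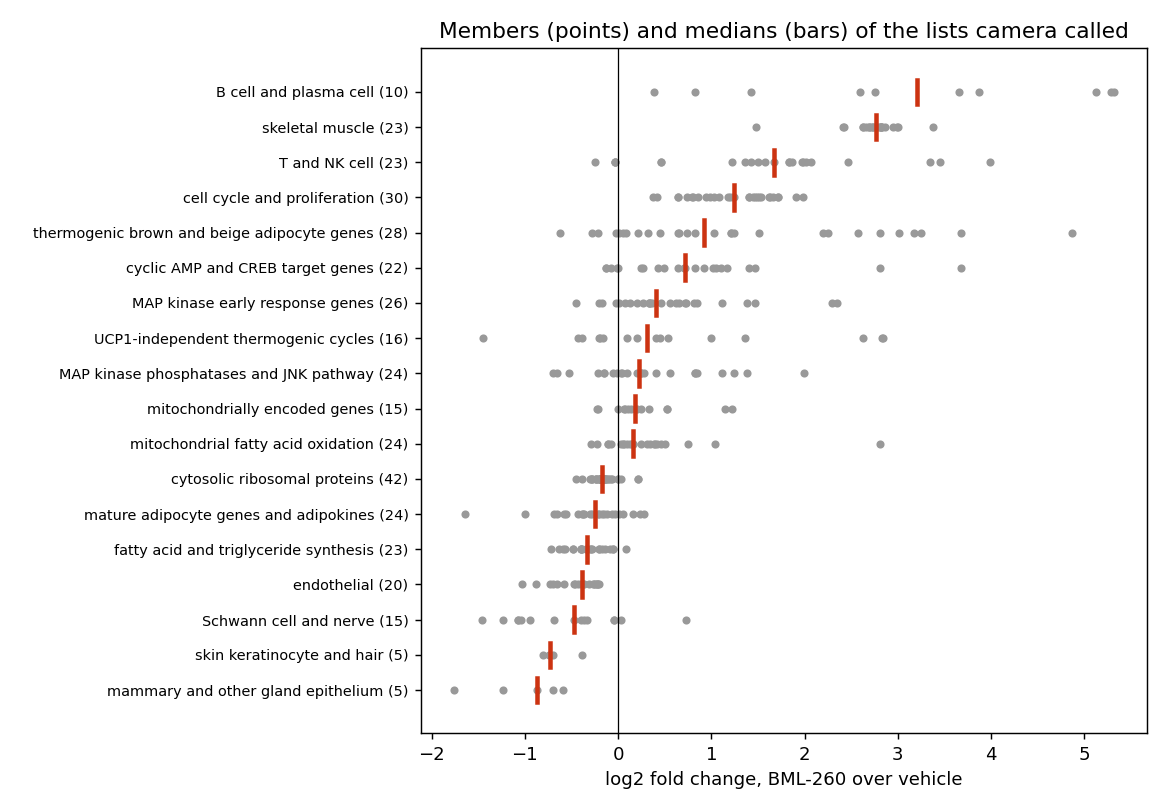
Log2 fold changes of the tested members (grey points, their number in brackets) and the median (red bars) of the 18 gene lists called by camera at its preset correlation. Medians run from -0.87 for gland epithelium to 3.20 for B cells, and 0 of the 18 lists kept an adjusted p under 0.05 with an estimated correlation.

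Skeletal muscle markers rose as a group (median 2.77 over 23 members, 23 above zero, camera adjusted p = 4.4e-10; adjusted p = 0.86 with an estimated correlation). Among its members 0 passed the edgeR test over all genes or adjusted over the list alone, 6 reached an unadjusted p under 0.05 and DESeq2 called 0. The list took 0.0586% of counts in vehicle A, 1.40% in vehicle B, 4.15% in BML-260 A and 5.59% in BML-260 B, so the vehicle libraries differed from each other as well. Ckm, the muscle creatine kinase gene, lay at 42.6, 1476, 4019 and 6304 CPM in that order. Myh1, Des, Tcap and Mb had log2 fold changes of 2.41, 2.42, 3.38 and 1.48, with edgeR adjusted p between 0.367 and 0.427. The median was 1.842 without vehicle A and 6.521 without vehicle B.

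Lymphoid markers were high in BML-260 A. The B cell list rose as a group (median 3.20 over 10 members, 10 above zero, camera adjusted p = 0.0285; adjusted p = 0.895 with an estimated correlation), with 6 members at an unadjusted p under 0.05 and 0 called by edgeR, by DESeq2 or adjusted over the list alone. Cd79a, part of the B cell receptor, lay at 0.285 and 0.692 CPM in vehicle, at 38.1 in BML-260 A and at 0.911 in BML-260 B. Cd22 had the same form, with 33.9 in BML-260 A and 0.638 in BML-260 B, and Igkc and Jchain had log2 fold changes of 2.59 and 1.43. The T and NK cell list also rose as a group (median 1.67 over 23 members, 19 above zero, camera adjusted p = 0.0332; adjusted p = 0.895 with an estimated correlation), with 3 at an unadjusted p under 0.05 and 0 called by edgeR, by DESeq2 or adjusted over the list alone. Il7r, Tcf7 and Cd28 lay at 20.6, 25.4 and 5.63 CPM in BML-260 A and at 1.78, 0.911 and 3.10 in BML-260 B, and Ccr7 had a log2 fold change of 3.46. Without BML-260 A the medians were 0.37 for B cells (adjusted p = 0.558) and -0.23 for T and NK cells (adjusted p = 0.850). Without vehicle A the T and NK cell list had an adjusted p of 0.317. Medians were 5.575 and 2.717 for B cells and for T and NK cells without vehicle B, and 6.061 for B cells without BML-260 B. Both calls were lost with the muscle term (adjusted p = 0.0538 and 0.685), with medians of 2.938 and 0.901.

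Cell cycle genes rose as a group (median 1.24 over 30 members, 30 above zero, camera adjusted p = 4.48e-09; adjusted p = 0.86 with an estimated correlation). None passed the edgeR test over all genes or adjusted over the list alone, DESeq2 called 0, and 11 reached an unadjusted p under 0.05. Top2a lay at 4.37 and 9.81 CPM in vehicle, 30.8 in BML-260 A and 13.3 in BML-260 B. Bub1, Prc1 and Kif11 had log2 fold changes of 1.99, 1.71 and 1.40, each also with its highest value in BML-260 A, the library with the high lymphoid markers. Without that library the list's median was 0.48 (camera adjusted p = 3.42e-05), and with the muscle term it was 0.74.

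**Figure D3:**
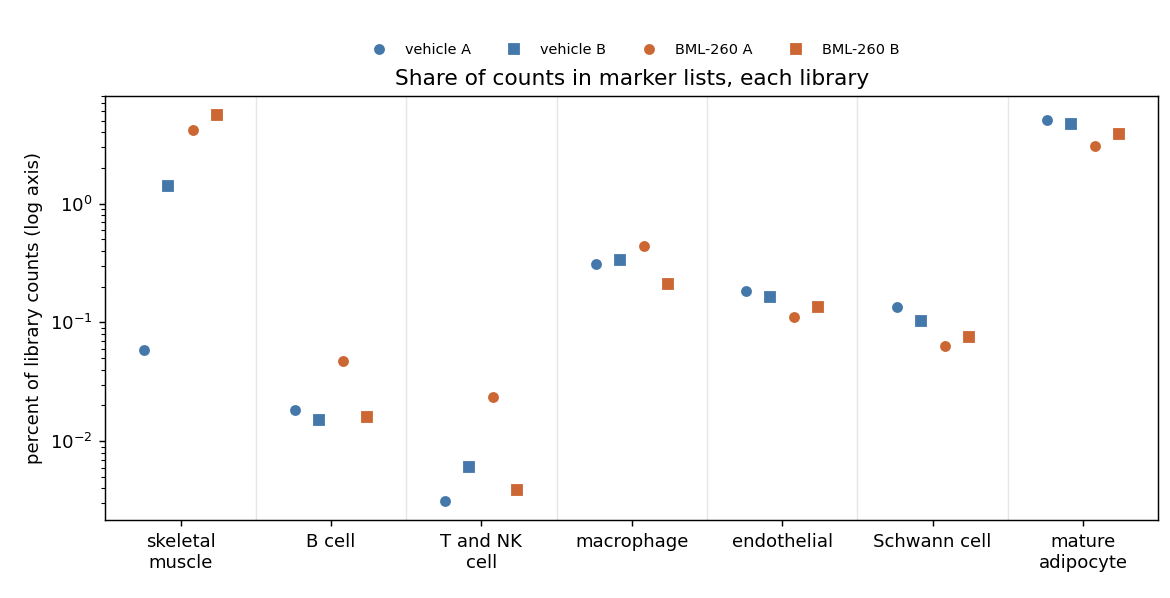
Percent of each library's counts taken by 7 marker lists on a log axis, 1 point per library (circles for A, squares for B, blue for vehicle, orange for BML-260). The skeletal muscle list runs from 0.0586% in vehicle A to 5.59% in BML-260 B, and the T and NK cell list takes 0.0237% in BML-260 A against 0.00314% to 0.00601% in the other libraries.

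Several other lists fell as groups. Endothelial markers had a median of -0.38 with 20 of 20 members below zero (camera adjusted p = 3.74e-08; adjusted p = 0.86 with an estimated correlation); Cldn5, Esam, Egfl7 and Gpihbp1 had log2 fold changes of -1.03, -0.70, -0.66 and -0.73. Schwann cell markers had a median of -0.47 over 15 members (camera adjusted p = 1.53e-04; adjusted p = 0.86 with an estimated correlation), with the myelin genes Mbp and Ncmap at -1.07 and -1.45 and Sox10 at -0.94. In both lists 6 members were lower at an unadjusted p under 0.05 and 0 passed the edgeR test over all genes or adjusted over the list alone; DESeq2 called 1 endothelial and 3 Schwann cell genes. The endothelial median was -0.219 without BML-260 A and -0.66 without BML-260 B. The Schwann cell median was -0.261 without vehicle A, -0.707 without vehicle B and -0.97 without BML-260 B, and its call was lost with the muscle term (adjusted p = 0.257, median -0.098). Gland epithelium had a median of -0.87 (camera adjusted p = 0.00135; adjusted p = 0.86 with an estimated correlation) and keratinocyte markers of -0.73 (camera adjusted p = 0.00585; adjusted p = 0.86 with an estimated correlation), over 5 tested members each. Of the gland list edgeR called 0 over all genes and 1 adjusted over the list alone, Trp63 (log2 fold change -1.23), which was also the 1 that DESeq2 called; 3 were lower at an unadjusted p under 0.05, with Cldn3, Prlr and Krt19 at -1.76, -0.59 and -0.87. Of the keratinocyte list, edgeR called 0 over all genes or adjusted over the list alone, DESeq2 called 0 and 0 were lower at an unadjusted p under 0.05, with Dmkn, Krt10, Perp and Krtdap between -0.69 and -0.81. The gland call was lost without BML-260 A (adjusted p = 0.0734), with medians of -0.561 without vehicle A, -1.384 without BML-260 B and -0.541 with the muscle term. The keratinocyte call was lost without BML-260 B (0.110) and with the muscle term (0.0538), both with a median of -0.529. Ribosomal protein genes had a median of -0.17 with 38 of 42 below zero (camera adjusted p = 5.93e-05; adjusted p = 0.895 with an estimated correlation), with 0 called by edgeR over all genes or over the list alone, 2 at an unadjusted p under 0.05 and 1 by DESeq2; Rplp2, Rps19 and Rps28 had -0.46, -0.39 and -0.31. Their call was lost without BML-260 B (adjusted p = 0.167, median -0.055) and with the muscle term (0.729, median 0.018), and the median was -0.113 without vehicle A and -0.33 without BML-260 A.

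Among the lists that camera did not call, fibroblast and adipocyte progenitor markers had a median of 0.02 over 24 members (adjusted p = 0.570), smooth muscle and pericyte markers -0.03 over 16 (0.321), neutrophil markers -0.30 over 7 (0.687), mast cell and eosinophil markers -0.16 over 9 (0.565), erythrocyte and platelet markers 0.02 over 9 (0.739) and lymph node stroma 0.13 over 6 (0.850). Extracellular matrix genes had a median of 0.14 over 37 members (camera adjusted p = 0.802), cholesterol synthesis -0.04 over 21 (0.867), the interferon response -0.05 over 34 (0.0955), MHC class II and antigen presentation -0.15 over 15 (0.321), the heat shock response 0.13 over 16 (0.192), the NRF2 response -0.11 over 20 (0.338) and hypoxia and angiogenesis -0.11 over 23 (0.338). Some of these lists were called at the preset correlation with 1 library left out, which leaves 1 library in a group. Without BML-260 A they were the fibroblast (median -0.231), MHC class II (-0.416), interferon (-0.174) and erythrocyte lists (0.501). Without BML-260 B they were the erythrocyte (-0.954), smooth muscle (-0.227), hypoxia (-0.139) and lymph node stroma lists (0.373). The last had Glycam1 as an added member that the filter removed with all libraries in. Without vehicle B it was the mast cell list (-0.406). With all libraries and an estimated correlation the camera adjusted p of each of these lists was 0.895 or 0.945. Other medians changed sign without passing the threshold: extracellular matrix (-0.134 without BML-260 A, -0.052 without vehicle A), neutrophil (0.373 without vehicle B, 0.376 without BML-260 B), lymph node stroma (-0.539), smooth muscle (0.111) and hypoxia (0.025) without BML-260 A, MHC class II (0.251) and interferon (0.015) without BML-260 B, fibroblast (-0.096) and mast cell (0.16) without vehicle A, and cholesterol synthesis (0.063) and erythrocyte (-0.061) without vehicle B. The Y-linked gene Ddx3y lay between 67.1 and 86.4 CPM in all 4 libraries.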

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

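The muscle score as a term, the robust prior and the thermogenic list without muscle-expressed members were chosen after seeing the data; the other alternatives were fixed before the data were examined. Across all of them the number of genes called ran from 0 to 651. DESeq2 called 405 (327 higher, 78 lower) and edgeR without a count filter 651 (565 higher, 86 lower), where the added low-count genes raised the prior degrees of freedom from 3.28 to 13.7; 361 of the 651 were among DESeq2's calls. The robust prior called 2, Ucp1 and Dio2, both higher. The muscle term called 0, with 416 at an unadjusted p under 0.05. RLE factors, library totals, limma-voom, a mean count of 50, an adjusted p under 0.10 and a 2-fold minimum each called 1 gene, higher. Leaving out 1 library gave 0 to 309 calls, 0 to 300 higher and 0 to 9 lower, with the lone library of a group assumed to vary like the other group: 0 without vehicle A, 309 without vehicle B (22 of them skeletal muscle genes), 1 without BML-260 A and 5 without BML-260 B. The log2 fold change of Ucp1 lay between 4.59 and 5.02 under every alternative.

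The labels do not say that the letters pair the samples. Deviations of same-letter libraries from their group means had a correlation of -0.059 across 15643 genes, which are not independent replicates, so this value does not settle it. With the letter as a replicate block edgeR called 0 genes (0 higher, 1468 at an unadjusted p under 0.05) and camera 18 lists.

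Of 40 lists, camera called 18 at its preset correlation, 0 with an estimated correlation, where 1 had an unadjusted p under 0.05, and fry called 0, with 5 at an unadjusted p under 0.05. That 1 was the thermogenic list (unadjusted camera p = 0.0349 at an estimated correlation of 0.067, unadjusted fry p = 0.00575). The skeletal muscle list had an unadjusted camera p of 0.24 at an estimated correlation of 0.866. Adjustment over all lists gave both 0.86. The muscle term left 7, the thermogenic, CREB, MAP kinase early response, cell cycle, fatty acid synthesis, endothelial and gland lists. Leaving out 1 library gave 15 to 22. The median of all genes was 0.02 with TMM, 0.01 with RLE and -0.04 with library totals.

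Some directions reversed, and the cause was not tested. With the muscle term, the medians of the skeletal muscle list and the ribosomal protein list became -0.182 and 0.018, the first by construction, and Krt19 and Lep had 0.04 and 0.285. Of the lists not called, the mast cell (0.479), extracellular matrix (-0.092), interferon (0.075), nuclear oxidative phosphorylation (-0.051) and fibroblast (-0.035) medians also changed sign with it. Leaving out 1 library at a time gave -0.226 to 2.717 for the T and NK cell list, -0.514 to 4.291 for Tcf7, -0.632 to 0.167 for Fasn, -0.08 to 0.033 for Dusp22 and -0.133 to 0.406 for Socs3, each with the changed sign without BML-260 A. Fasn and Creb1 also changed sign without vehicle B (0.011 and -0.021), and Creb1, from -0.021 to 0.351, without BML-260 A as well (-0.005). Without BML-260 B the fatty acid oxidation list (-0.023 to 0.323) and Prdm16 (-0.151 to 0.279) changed sign. Depth was not the main limit for Ucp1, with at least 166 reads per library.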

Other observations

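The genes named in this and the next paragraph, and the tests of the muscle, brown fat and lymphoid explanations, were chosen after the gene and list results had been seen. Genes of fat release and lipid droplets went both ways: the median of the list was -0.25 over 20 members (camera adjusted p = 0.338), with 4 members higher and 3 lower at an unadjusted p under 0.05. Adrb1, a beta-adrenergic receptor gene, lay at 3.70 and 3.54 CPM with vehicle and 7.51 and 8.02 with BML-260. Plin5, a lipid droplet protein of oxidative tissues, had a log2 fold change of 0.89 (SE 0.14), while G0s2, an inhibitor of the lipase ATGL, had -0.50 (SE 0.16). Clock genes had a median of 0.38 over 18 members (camera adjusted p = 0.338), with Hlf, Dbp and Per3 at 0.99, 0.89 and 0.82 and Npas2, Nfil3 and Arntl at -2.06, -0.75 and -0.77. Glucocorticoid targets had a median of 0.22 over 18 members (camera adjusted p = 0.0925), with Pdk4 and Tsc22d3 at 2.20 and 0.70 and Fkbp5 at -1.18. In edgeR's test over all genes 0 members of these 3 lists passed; at an unadjusted p under 0.05 there were 7, 9 and 6, DESeq2 called 3, 2 and 3, and 4, 1 and 2 were higher adjusted over the list alone. At the preset correlation and with 1 library left in a group, camera called each of them with 1 library left out. The lipolysis list was called without BML-260 B (median -0.465), and had -0.045 without BML-260 A. The clock list was called without BML-260 A (0.532), and had 0.108 without BML-260 B, 0.158 without vehicle A and 0.053 with the muscle term. The glucocorticoid list was called without vehicle B (0.371), and had 0.091 without BML-260 A and 0.08 with the muscle term. With all libraries and an estimated correlation their camera adjusted p was 0.92, 0.895 and 0.86.

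Macrophage markers had a median of 0.14 over 28 members (camera adjusted p = 0.739). Arg1, which encodes arginase 1, had a log2 fold change of 3.60 (SE 0.43), from 0.570 and 0.303 CPM to 6.07 and 4.56. Chil3, Trem2 and Gpnmb had 2.84, 1.45 and 1.36, each higher in BML-260 A than in BML-260 B, and Cd163, a marker of resident macrophages, had -0.58. Without BML-260 A the list's median was -0.28 and without BML-260 B it was 0.64. With all libraries and an estimated correlation its camera adjusted p was 0.945. Of the cytokine list (median 0.27 over 25 members, camera adjusted p = 0.406, or 0.895 with an estimated correlation) Spp1 and Il1rn had 1.89 and 1.83. The cytokine list's median was 0.719 without BML-260 B but -0.07 without BML-260 A. The stress response list had a median of -0.07 over 28 members (camera adjusted p = 0.813), with Vldlr, Atf3 and Sesn2 at 0.96, 1.40 and 0.62 and Asns at -0.51. No member of these 3 lists passed edgeR's test over all genes; 6, 5 and 6 did at an unadjusted p under 0.05, DESeq2 called 4, 2 and 2, and 1, 0 and 1 were higher adjusted over the list alone.

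Skeletal muscle dissected along with the fat to different degrees is a candidate explanation for the muscle markers. The list's median was 24.7-fold higher in vehicle B than in vehicle A, a difference within 1 treatment, and its members kept nearly 1 ratio between vehicle B and the BML-260 mean (3.65-fold, SD of the log2 ratio 0.181 over members), as mixing in 1 tissue would give. Between the vehicle libraries the members did not keep 1 ratio. Vehicle B over vehicle A was 0.58 for Mb, 5.90 for Myh1, 6.43 for Des and 16.9 for Tcap, and above 1.5 for 22 of the 23 members. The higher share in both BML-260 libraries leaves an effect of treatment open as well, and that was not tested.

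Muscle in the sample could also bring thermogenic transcripts, so the level expected from muscle alone was read from a line through the 2 vehicle libraries against their muscle transcripts. As a check, 11 muscle genes were left out of a line built on the other muscle genes. Their median was 1.09 and 1.07 times the expected level in BML-260 A and B. Ucp1 stood at 19.0 and 16.5 times its expected level, and at 13.7 and 11.066 times the upper 95% counting limit of it, which argues against muscle as the source of Ucp1. For the other 27 thermogenic members a plain line floored at 0, run first, gave a median log2 ratio of observed to expected of 0.78. Its 95% bootstrap interval was 0.55 to 1.21, above 0 and so against muscle. That line let 10 members lower in vehicle B than in vehicle A drop with muscle. In CPM, a share of each library, added muscle RNA can lower the values of other genes. Slopes held at 0 or more, tried next as if muscle only added RNA, gave 0.40 (-0.044 to 0.78), which did not exclude muscle. Single muscle genes varied in that form. Mb, lower in vehicle B than in vehicle A, stood at 1.64 and 2.75 times its expected level in BML-260 A and B, and Tcap at 1.41 and 1.66. Myh1 stood at 1.13 and 0.84 and Des at 0.98 and 0.91. Holding slopes raises expected levels in general, with a median log2 ratio of -0.217 for genes of like vehicle level. A comparison with those genes was added after both forms had been seen. Against them the members stood at 0.61 (0.161 to 0.99), and at 0.76 (0.37 to 1.23) with the plain line. With the muscle score as a term their median log2 fold change was 0.83 (0.31 to 1.69) against 0.82 without it. The score is a log2 level (-4.025 and 0.123 in vehicle A and B, 1.671 and 2.231 in BML-260 A and B). Muscle mixed in would add to counts instead. The term can thus remove too little from a gene that muscle supplies in part, so the unchanged median does not decide the question. This fit leaves 1 residual degree of freedom. The muscle list had -0.18 (-0.39 to 0.15) in it by construction, since the score is the mean of that list, so this does not test the term. Set against genes of like level, the 27 members argue against muscle as the whole source of the rise, as does the plain line. The held slopes alone did not exclude muscle. With them 5 of the 27 stood above 2 times their expected level in both BML-260 libraries, and 10 with the plain line. A share of the rise from muscle in single members stays open, and the intervals cover the spread over members, not between libraries.

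Brown adipose tissue dissected along is another candidate explanation for Ucp1. A first test on Lhx8, Mpzl2 and Epsti1 gave log2 ratios of -0.28, -0.02 and 0.74, whose median of -0.02 met the criterion against this explanation, but it was set aside after its result was seen, since these genes have a baseline in white fat that would hide a small share of brown fat. Zic1, a classical brown marker with a low baseline, had 7 reads in the vehicle libraries and 21 in the BML-260 libraries, a ratio of 3.104 (exact Poisson 95% interval 1.27 to 8.64). With 1, 6, 5 and 16 reads in vehicle A, vehicle B, BML-260 A and BML-260 B the groups overlapped when scaled to depth, and so few reads keep the question open.

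Lymphoid tissue in BML-260 A, such as a piece of the lymph node embedded in this depot, is a candidate explanation for the rise in cell cycle genes, which peak in that library. Of the 6 tested lymph node stroma genes, Ccl19 (265 reads) and Ccl21a (1177) were highest there, against 40 to 64 and 96 to 224 in the other libraries, but Lyve1, Cxcl13, Enpp2 and Prox1 did not have their most reads there; Glycam1, a gene of lymph node venules and the mammary gland that the filter removed, had 171 reads there and 0 elsewhere. Without BML-260 A the median log2 fold change of the cell cycle list was 0.48 against 1.24 with it, a drop that any feature of that library would give. In BML-260 B, whose lymphoid markers were near the vehicle libraries, the members lay a median log2 ratio of 0.178 above vehicle B (95% bootstrap interval 0.07 to 0.32), while the vehicle libraries differed by 0.64 between themselves. A rise in BML-260 B alone and within that spread does not decide between lymphoid tissue and an effect of treatment, so the 2 cannot be told apart here.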
